A study of Homo sapiens with 4 samples.

How the data were processed

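RNA of single HCA2 human skin fibroblasts was measured by Drop-seq in 4 libraries, 1 each of low PD cells, low PD cells after 50 Gy, high PD cells and replicative senescent cells, which the labels give at passages 38, 38, 48 and 71. The replicative senescent library carries no treatment in its label. The deposited values are UMI counts per gene and cell barcode, 400 barcodes per library, made by the authors. The submitters' processing notes name STAR 2.5.3a and the genome build GRCh37. The gene annotation, the strand counted, the collapsing of UMIs and the choice of barcodes are not given in the sources used here, so counts of a gene with an overlapping antisense gene may include that gene.

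Barcodes with at least 500 genes and at most 20% of UMIs from mitochondrially encoded genes were kept, which left 394, 400, 397 and 374 cells, 1565 in all, with 7078915 UMIs over 19886 genes. UMIs were summed per library and gene and divided by the library total to give CPM, with exact Poisson intervals at 95%. A count of 3 was taken as the floor, which is 1.93 CPM in low PD, 1.56 in irradiated, 1.54 in high PD and 1.83 in replicative senescent cells. A log2 ratio used 0.5 added to each summed count, and its interval is the exact conditional binomial (Clopper-Pearson) interval of 2 Poisson counts. A gene with 0 counts in 1 library is given as at least a fold, the count of the other library against the floor. The counting error of that other count is left out, so this fold is not a 95% bound. Intervals cover counting error, not the spread between cultures. Each gene list was described by the median log2 ratio of its members with at least 20 UMIs over the pair of libraries, the order-statistic interval of that median, the members on each side of 0, and its percentile among 10000 random lists matched on expression from the 100 genes on either side of each member. Lists with fewer than 3 measured members are given as UMIs. There were 34 lists.

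The comparisons, the lists, the filters, the first set of alternatives and the rule for named genes were fixed before the data were examined. By that rule, among genes with at least 100 UMIs over the pair and a mean of at least 50 CPM, the 10 highest and 10 lowest log2 ratios, ranked by the bound nearest 0, were named in each of the first 3 comparisons and the 5 highest and 5 lowest in the others, with up to 4 members of each list, those of the largest ratio among members of at least 100 UMIs, and a fixed set of senescence genes. Clone-named, Y-linked and mitochondrially encoded genes were left out of the ranking. Some genes that the rule names are not reported here, and no others took their places.

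For comparisons of single cells every cell was thinned to 2000 UMIs, the highest depth of 500, 1000, 2000, 3000 and 5000 that at least 60% of cells of every library reached. This kept 295, 352, 330 and 263 cells. Shares of cells have exact Clopper-Pearson intervals, and for a share of 0 the limit is 3 counts of the cells. Spread was the median Pearson correlation of log1p counts between pairs among 263 cells per library over 1000 genes, with jackknife intervals over 10 blocks of cells. Clusters came from 2000 variable genes, 20 principal components, 15 neighbours and Leiden resolution 0.5. Leading axes came from principal components within each library. The splits into 2 sides used 2-means on 10 components from 1000 genes in each of 2 disjoint sets, divided 20 times, and compared the cells put on the same side by both. Likeness of the irradiated and replicative senescent profiles used genes with at least 50 UMIs and 100 Poisson draws of all 4 libraries, as unchanged groups, from 1 profile pooled over them.

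No doublets were removed. Scrublet called 7, 1, 7 and 13 barcodes, and 81, 84, 57 and 79 had over 2 times the median UMIs of their library. Pairs of barcodes 1 base apart, 28, 37, 5 and 14, were counted as separate cells. In the low PD and irradiated libraries all differed at the last base, with a median UMI ratio within pairs of 1.31 and 1.32, and in the high PD and replicative senescent libraries none did, with 12.1 and 14.2. They were merged as an alternative.

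The methods were tested on simulated data, with expression pooled over the 4 libraries. For the ratios the totals were those of the replicative senescent and low PD libraries. Changed genes were drawn from those with at least 100 expected UMIs over the pair. Counts were Poisson draws, so coverage and recovery hold for counting error only and not for genes with many UMIs in 1 barcode. Of genes given a true 2-fold difference among 9912, 99.0% were recovered with 95.8% coverage of the interval, and of those given a 4-fold difference among 9846, 100.0% with 96.1%. Of 400 unchanged lists, 24 and 22 lay outside the central 95%. These were random genes drawn independently, so this does not cover lists whose members vary together. A single simulated population gave a correlation between cells of 0.5452 whether shallow or deep after thinning, and split cells on the same side in 54.0% and 51.6% of cases, against 100.0% for 2 populations. A gradient was not simulated.

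The alternatives were all deposited barcodes; at least 1000 genes and at most 10% mitochondrial UMIs; trimmed mean of M-values factors from edgeR 4.0.16; median-of-ratios size factors as in DESeq2 1.42.0; totals without mitochondrial and ribosomal protein genes; the mean of CPM over cells; removal of Scrublet calls or of barcodes over 2 times the median; 3 added to each count; list minimums of 1 and 100 UMIs; and a random draw of 50% of the cells. Further ones were a thinning depth of 1000 UMIs, 300 genes, other Leiden resolutions (0.25 and 1.0), removal of the cell cycle lists and 200 UMIs for likeness. Removal of each library's barcode with the most G2/M UMIs, the merging of barcodes and the splits were added after the data were seen. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9, and in R 4.3.3. Differential expression was not tested, since no group had a replicate. The splits of high PD cells (73.3% on the same side) are not described.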

Results

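Single human skin fibroblasts of the HCA2 culture were profiled in 4 states by Drop-seq, a droplet method in which the polyadenylated RNA of each cell is captured on a barcoded bead and counted by unique molecular identifiers (UMIs). Low PD cells, a culture of low population doubling, were taken at passage 38, and cells of the same passage were also profiled after 50 Gy of ionizing radiation. High PD cells were at passage 48 and cells described as replicative senescent at passage 71. By its title the series sets senescence reached by repeated division beside senescence brought on by radiation. Each state was 1 library of 400 barcodes. The libraries kept 394 low PD, 400 irradiated, 397 high PD and 374 replicative senescent cells, with 1555519, 1928446, 1951095 and 1643855 UMIs in total and medians of 2700.5, 2755.5, 3860.0 and 3114 UMIs per cell. With 1 library per state there were no replicates, so no difference could be tested or checked against the spread between cultures. Expression is given as CPM, the UMIs of a gene scaled to a common library total. An interval beside a gene's CPM, its log2 ratio or a share of cells is a 95% interval that covers counting error only, and one beside a list is the order-statistic interval of the median over its members.

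The libraries differed in overall composition. Cytosolic ribosomal protein genes took 17.3% of the UMIs in low PD cells, 11.3% after irradiation, 11.4% in high PD cells and 6.74% in replicative senescent cells. The nuclear noncoding RNA MALAT1 took 2.74%, 1.63%, 3.06% and 3.54%, and all mitochondrially encoded genes in the data 3.77%, 3.78%, 3.37% and 2.62%. The list of that name used below holds 13 of these genes, at 18310, 20713, 19851 and 17660 CPM. Over all genes with at least 20 UMIs in the pair, the median log2 ratio to low PD was 0.10 after irradiation, 0.10 in high PD cells and 0.19 in replicative senescent cells. Scaling by trimmed mean of M-values moved these medians to -0.01, -0.02 and -0.01, shifts of over 0.1, so each list median below is to be read against the median of all genes in its comparison. Some barcodes differed from another barcode of their library at 1 base. There were 28 such pairs in low PD cells, 37 in irradiated cells, 5 in high PD cells and 14 in replicative senescent cells, where 0.17 were expected by chance. Joining them left 379, 381, 392 and 361 cells and kept every list median within its interval. All pairs of low PD and irradiated cells differed at the last base, and none of high PD and replicative senescent cells did. Comparisons of high PD or replicative senescent cells with low PD or irradiated cells cross this technical difference. It cannot be told apart from passage.

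Transcripts of immune, endothelial, melanocyte and erythroid cells were few, while pericyte and smooth muscle markers were not. The latter held 747 UMIs in low PD cells, 1332 after irradiation, 1594 in high PD cells and 743 in replicative senescent cells. Of these, ACTA2, also in the contractile list, made up 629, 1023, 1204 and 410. Immune markers held 32 UMIs in low PD cells, 170 after irradiation, 33 in high PD cells and 7 in replicative senescent cells, mostly SRGN, a proteoglycan that fibroblasts can also express (32, 155, 31 and 4 UMIs), and PTPRC, the pan-leukocyte antigen, had 0, 3, 2 and 2. Endothelial markers held 14, 33, 23 and 13 UMIs, melanocyte markers 47, 71, 44 and 49, nearly all MITF, and erythroid markers 0, 2, 1 and 2. Keratinocyte markers held 542, 1521, 693 and 727 UMIs, of which PERP, also a transcriptional target of p53, made up 332, 1195, 477 and 528 and KRT10 206, 305, 208 and 188.

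**Figure D1:**
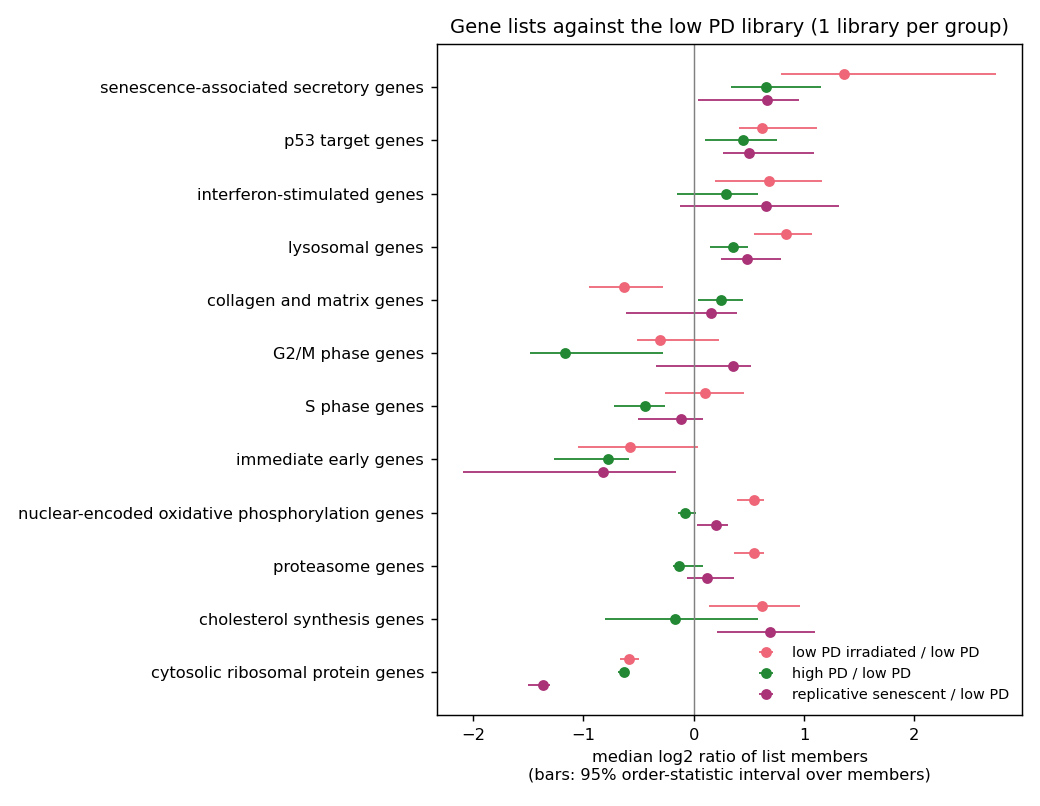
Median log2 ratio of the measured members of 12 gene lists (horizontal axis) in irradiated, high PD and replicative senescent cells, each against low PD cells. Points are medians, bars are 95% order-statistic intervals over the members, 1 library per group. Senescence-associated secretory genes lie highest after irradiation (1.36) and cytosolic ribosomal protein genes lowest in replicative senescent cells (-1.37).

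Irradiated cells were compared with unirradiated cells of the same passage, to ask what differed after 50 Gy. Library and treatment cannot be told apart. Genes of the senescence-associated secretory list, the inflammatory and proteolytic factors that senescent cells release, were higher, with a median log2 ratio of 1.36 (0.79 to 2.74) and 34 of 43 members higher. IL8, a neutrophil chemokine found in 80 irradiated cells, stood at 143 CPM (127 to 161) after irradiation and 1.29 (0.156 to 4.64) in low PD cells, and SERPINB2, a plasminogen activator inhibitor, at 204 CPM (185 to 226) and 1.93 (0.398 to 5.64). The chemokine genes CXCL6 (log2 ratio 6.95, 5.62 to 9.46) and CXCL1 (6.35, 4.80 to 9.73) were higher too. However, 69.5% of the CXCL6 UMIs and 31.6% of the CXCL1 UMIs came from 1 barcode. CCL5, at least 68.8-fold higher, rested almost wholly on 1 barcode, which held 91.8% of its 256 UMIs. The collagenase MMP1 was at 59.6 against 1.93 CPM (log2 ratio 4.73, 3.37 to 7.25). IL6 was at 39.4 against 36.0 CPM (0.13, -0.39 to 0.66), a difference not detectable at this depth.

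Targets of p53, the transcription factor activated by DNA damage, had a median log2 ratio of 0.62 (0.41 to 1.12), with 27 of 33 members higher. CDKN1A, the cyclin-dependent kinase inhibitor that halts the cycle downstream of p53, was at 641 CPM (606 to 678) against 222 (199.6 to 247, log2 ratio 1.53, 1.35 to 1.70). The stress-induced factor GDF15 had a log2 ratio of 3.21 (2.63 to 3.92), GADD45A 1.56 (1.37 to 1.76) and MDM2, the ubiquitin ligase of p53, 1.12 (0.84 to 1.42). PERP, counted among the keratinocyte markers, was at 619.7 against 213 CPM. CDKN2A was at 24.9 and 32.1 CPM (-0.37, -0.97 to 0.23), not detectably different. Interferon-stimulated genes had a median of 0.68 (0.20 to 1.16, 28 of 37 higher), among them IFI6 (3.66, 3.27 to 4.11), IFIT2 (2.13, 1.39 to 3.03), ISG15 (2.04, 1.64 to 2.49) and LY6E (1.25, 1.04 to 1.48). The MHC class I list had 0.38 (0.17 to 0.74), with B2M at 1.35 (1.29 to 1.42).

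Lysosomal genes were higher, with a median of 0.84 (0.54 to 1.07) and 40 of 47 members higher. Among them were ATP6V1H (1.78, 1.16 to 2.49), ATP6V0E1 (1.71, 1.52 to 1.90), the cathepsin CTSB (1.66, 1.56 to 1.76) and GLB1 (1.39, 0.85 to 2.0), which encodes the lysosomal beta-galactosidase used to stain senescent cells. Genes of oxidative phosphorylation encoded in the nucleus (0.55, 0.39 to 0.64, 61 of 67 higher), proteasome genes (0.55, 0.36 to 0.64, 26 of 29), glycolysis genes (0.49, 0.26 to 0.80, 18 of 20), cholesterol synthesis genes (0.62, 0.14 to 0.96, 15 of 19) and heat shock genes (0.62, 0.18 to 0.98, 14 of 15) were higher as groups. In the antioxidant list, with a median of 0.42 (-0.16 to 0.96), the metallothionein MT2A (2.31, 2.23 to 2.38) and the mitochondrial superoxide dismutase SOD2 (2.25, 2.05 to 2.47) were highest. Histone genes had a median of 1.55 (-0.41 to 2.90) over 10 measured members, with the linker histone HIST1H1C at 2.99 (2.19 to 4.04) and HIST1H2BK at 2.90 (2.33 to 3.59). The replication-dependent HIST1H4C was lower, at -2.06 (-2.27 to -1.86), with 22.2% of its irradiated UMIs in 1 barcode. As a sum the histone list was lower after irradiation, at 746.2 CPM against 862.7 in low PD cells.

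Collagen and matrix genes were lower after irradiation, with a median of -0.63 (-0.95 to -0.28) and 41 of 55 members lower. COL1A1, the main fibrillar collagen of skin, was at 2989 CPM (2912 to 3067) against 9054 (8905 to 9204). COL3A1 was at 527 against 1048 CPM. COL15A1 (-4.51, -5.18 to -3.95), MFAP4 (-4.49, -5.92 to -3.50), THBS2 (-2.72, -3.03 to -2.43) and MGP (-2.28, -2.71 to -1.89) were lower by more. Fibroblast markers, which share COL1A1 and 8 other members with that list, had a median of -0.46 (-1.60 to 0.20). Ribosomal protein genes were lower in 75 of 76 cases (median -0.59, -0.67 to -0.49), with RPL13 at -1.14 (-1.20 to -1.09). Immediate early genes had a median of -0.57 (-1.05 to 0.04), with FOS (-3.19, -3.49 to -2.91), FOSB (-2.45, -2.93 to -2.01) and EGR1 (-2.15, -2.42 to -1.90) lower. ATF3, with 25.2% of its irradiated UMIs in 1 barcode, was higher (2.54, 1.89 to 3.32). G2/M phase genes, expressed before and during mitosis, had a median of -0.31 (-0.52 to 0.23, 28 of 45 lower) and S phase genes 0.10 (-0.26 to 0.46). TOP2A was at 52.4 against 107 CPM (-1.02, -1.40 to -0.66) and MKI67 at 16.1 against 27.6 (-0.78, -1.50 to -0.08), with 26.7% and 22.6% of their irradiated UMIs in 1 barcode. HMGB2 had -0.52 (-0.91 to -0.13), and LMNB1, with 8 and 14 UMIs, -1.08 (-2.58 to 0.23).

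The remaining genes with the highest ratios were TFPI2, an inhibitor of matrix-degrading proteases (4.85, 4.28 to 5.54, with 23.1% of its irradiated UMIs in 1 barcode), and the YAP target ANKRD1 (3.48, 3.07 to 3.95, with 36.2% of its 47 low PD UMIs in 1 barcode). They also included the G protein regulator RGS4 (3.30, 2.94 to 3.69) and the tissue plasminogen activator PLAT (3.11, 2.89 to 3.35). Those with the lowest were EGFL6 (-5.06, -5.87 to -4.42), the growth factor IGF2 (-3.92, -4.19 to -3.66), the cartilage proteoglycan ACAN (-3.58, -4.43 to -2.89), AARD (-3.34, -4.10 to -2.71), the transcription factor MAF (-2.89, -3.36 to -2.47), SBF2-AS1 (-2.77, -3.26 to -2.34) and the chemokine CXCL12 (-2.72, -3.06 to -2.41). The contractile list had a median of 0.40 (0.06 to 0.96) beside ACTA2 at 0.39 (0.25 to 0.54) and the pericyte and smooth muscle markers at 0.39 (-0.21 to 1.53). Medians lay at 0.46 (-0.07 to 0.96) for the unfolded protein response, 0.61 (-0.21 to 2.71) for the BCL2 family and 0.17 (-0.05 to 0.77) for YAP targets. They were 0.19 (-0.31 to 0.50) for mitochondrially encoded genes, -0.07 (-3.22 to 1.53) for cyclin-dependent kinase inhibitors (above 0 when every cell weighed the same) and -0.38 (-1.08 to 0.57) for genes known to be lower in senescent cells. Homologous recombination had -0.38 (-0.95 to 0.47), end joining 0.01 (-0.52 to 0.27) and telomere genes 0.27 (-0.21 to 0.93).

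Among 10000 random lists of equal size and matched expression, the medians of the secretory, interferon, lysosomal, oxidative phosphorylation and histone lists were at percentile 100. The p53 list was at 99.99, the matrix, ribosomal protein and immediate early lists at 0 and the G2/M list at 0.01. Genes known to be lower in senescent cells were at 1.10. Members of a list can vary together where random genes need not, so percentiles here and below are not read as tests. With members of at least 100 UMIs only, the medians of the secretory list and the interferon list were 0.86 and 0.23. The direction of the S phase median turned to -0.01 with trimmed mean scaling and that of the end joining median to -0.10, and that of homologous recombination to 0.21 with at least 1000 genes and at most 10% mitochondrial UMIs.

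**Figure D2:**
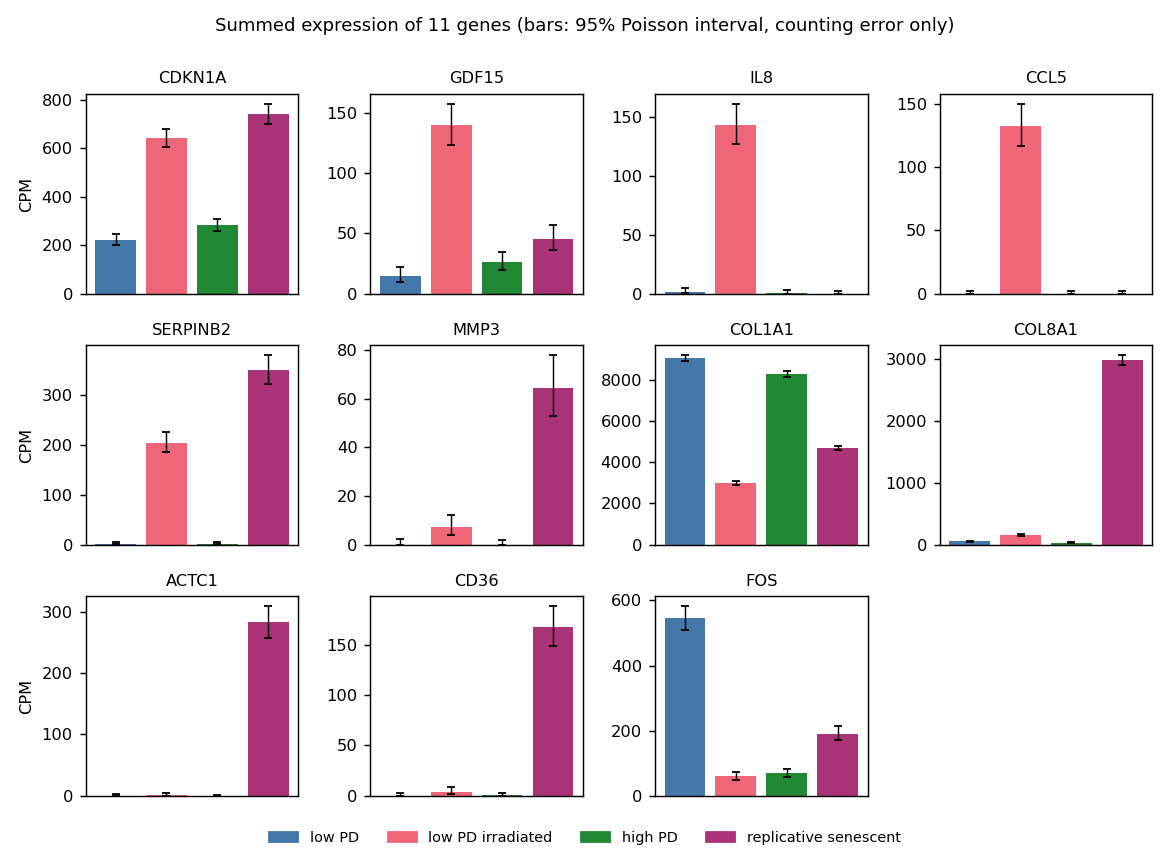
Summed expression in scaled UMIs (CPM, vertical axes from 0, each panel with its own scale) of 11 genes in the 4 libraries. Bars are 1 library each and error bars are exact 95% Poisson intervals. COL8A1 reached 2987 CPM in replicative senescent cells and 52.7 in low PD cells, and the CCL5 bar of irradiated cells rests on 1 barcode for 91.8% of its UMIs.

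Replicative senescent cells were compared with low PD cells, the latest passage with the earliest. Passage cannot be told apart from library or from the barcode difference given above. Several genes hardly counted in low PD cells were abundant. COL8A1, a short-chain collagen, was at 2987 CPM (2904 to 3072) against 52.7 (41.9 to 65.4, log2 ratio 5.82, 5.51 to 6.16). The microtubule regulator STMN2, known from neurons, was at 637 against 3.86 CPM (7.25, 6.24 to 8.82). SLC38A11, of an amino acid transporter family, was at 437 against 2.57 (7.24, 6.05 to 9.29). The cardiac actin gene ACTC1, the protocadherin PCDH10 and the fatty acid receptor CD36 had 0 UMIs in low PD cells and were at least 146-fold, 119-fold and 86.7-fold higher, against a floor of 3 counts. SERPINB2 (7.28, 5.95 to 9.79), the adhesion molecules AMIGO2 (6.34, 5.14 to 8.40) and CADM1 (5.73, 4.77 to 7.15), and LIMCH1 (5.0, 4.42 to 5.71) were also among the 10 highest. EGFL6, with 498 UMIs in low PD cells and 0 in senescent cells, was at least 175-fold lower. The imprinted gene MEST (-5.42, -6.99 to -4.39), the ligand WNT2 (-5.09, -5.92 to -4.44), CPA4 (-4.49, -5.47 to -3.74) and NFIB (-4.32, -5.55 to -3.44) were lower. So were PTX3 (-3.95, -4.29 to -3.64), FAM211A (-3.77, -4.24 to -3.37), FGF7 (-3.61, -3.98 to -3.28), CXCL12 (-3.54, -4.03 to -3.12) and IGF2 (-3.43, -3.68 to -3.20), which complete the 10 lowest.

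Every ribosomal protein gene measured was lower, 76 of 76 members, with a median log2 ratio of -1.37 (-1.51 to -1.30). RPS12, RPS16 and RPL23 had log2 ratios of -2.21 (-2.29 to -2.14), -2.21 (-2.32 to -2.10) and -2.19 (-2.28 to -2.10). Immediate early genes had a median of -0.82 (-2.09 to -0.16, 20 of 24 lower), with EGR1 (-3.44, -3.88 to -3.04), MYC (-2.87, -3.84 to -2.10), FOSB (-2.64, -3.19 to -2.15) and JUNB (-2.09, -2.43 to -1.77) among them. Secretory genes had a median of 0.66 (0.04 to 0.96, 24 of 35 higher) and p53 targets 0.50 (0.26 to 1.09, 25 of 34). Interferon-stimulated genes had 0.66 (-0.12 to 1.32, 22 of 35), lysosomal genes 0.48 (0.25 to 0.79, 39 of 46) and cholesterol synthesis genes 0.69 (0.21 to 1.10, 17 of 19). The secretory median was 0.33 with members of 1 UMI or more, 0.41 when every cell weighed the same and 0.42 without barcodes of over 2 times the median UMIs. With trimmed mean scaling the p53 median was 0.31 and the lysosomal median 0.28. CDKN1A was at 741 CPM (699.9 to 784) in replicative senescent cells, with a log2 ratio of 1.73 (1.56 to 1.91). CDKN2A, a tumour suppressor locus often higher in senescent cells, was lower, with 14 against 50 UMIs (-1.88, -2.89 to -1.04). MMP3 was at least 33.4-fold higher, NRG1 had 4.92 (3.88 to 6.49), MMP1 3.91 (2.49 to 6.44), and GDF15 1.60 (0.94 to 2.37). MDM2 had 1.09 (0.79 to 1.40) and IL6 -1.41 (-2.21 to -0.69). IL8 had 0 and 2 UMIs, too few for a ratio. The RNA sensor DDX58 (2.55, 1.87 to 3.36), IFITM1 (2.60, 1.92 to 3.41) and IFI6 (2.41, 1.99 to 2.87) were higher in the interferon list. GLB1 (1.74, 1.21 to 2.34), CTSZ (1.85, 1.47 to 2.26) and CTSO (1.61, 1.09 to 2.19) were higher in the lysosomal list.

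Collagen and matrix genes went both ways, with a median of 0.15 (-0.61 to 0.39) that turned to -0.04 with trimmed mean scaling. COL1A1 was at 4673 against 9054 CPM (-0.95, -0.99 to -0.91). COL3A1 had -0.69 (-0.80 to -0.57), FBN2 -2.32 (-2.69 to -1.97) and EFEMP1 -2.30 (-2.50 to -2.12), while COL11A1 had 3.94 (3.53 to 4.41). The contractile list had a median of 0.45 (-0.21 to 0.92), with CALD1 (2.21, 2.15 to 2.27), TPM1 (1.54, 1.44 to 1.64) and MYLK (1.22, 1.11 to 1.33) higher. CNN2 (-1.38, -1.65 to -1.11) and ACTA2 (-0.70, -0.88 to -0.52) were lower, beside pericyte and smooth muscle markers at 0.45 (-2.89 to 4.48). Histone genes had a median of 1.06 (-0.47 to 2.82) and heat shock genes 0.47 (0.12 to 0.84). G2/M phase genes had a median of 0.36 (-0.34 to 0.52), but 844 of their 2898 UMIs, 29.1%, came from a single barcode of 29051 UMIs. Without the top barcode of each library the median was -0.54, and it was -0.37 when every cell weighed the same. TOP2A (-0.55, -0.90 to -0.20) and MKI67 (0.19, -0.42 to 0.81) had 73.3% and 51.9% of their senescent UMIs in 1 barcode. HMGB2, with 23.2% in 1 barcode, had 0.17 (-0.19 to 0.54), and trimmed mean scaling turned both MKI67 and HMGB2 below 0. LMNB1 had -1.24 (-2.97 to 0.17). The median of S phase genes was -0.11 (-0.50 to 0.09), above 0 with members of at least 100 UMIs, and that of genes known to be lower in senescent cells -0.35 (-0.57 to 0.43).

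Against random lists, the median of the ribosomal protein and immediate early genes was at percentile 0 and that of the secretory list at 99.95. The interferon list was at 99.82, the histone list at 99.64, the p53 list at 97.66, the lysosomal list at 96.94 and the G2/M list at 87.93. Genes known to be lower in senescent cells were at 1.37. The remaining lists had medians of 0.20 (0.03 to 0.32) for oxidative phosphorylation encoded in the nucleus, 0.41 (-0.19 to 0.95) for MHC class I and 0.34 (0.00 to 1.15) for YAP targets. They were 0.39 (-0.38 to 1.58) for the BCL2 family, 0.68 (-1.95 to 1.73) for cyclin-dependent kinase inhibitors (below 0 when every cell weighed the same), 0.22 (-0.05 to 1.21) for end joining, -0.05 (-0.46 to 1.07) for telomere (above 0 with members of 1 UMI or more) and -0.08 (-0.53 to 0.40) for antioxidant genes. Those of mitochondrially encoded genes (0.03, -0.42 to 0.39), glycolysis (0.09, -0.48 to 0.42) and proteasome (0.12, -0.07 to 0.36) turned below 0 with trimmed mean scaling, as did those of the unfolded protein response (0.15, -0.27 to 0.55), homologous recombination (0.00, -0.87 to 1.17) and fibroblast markers (0.04, -0.95 to 0.29).

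High PD cells were compared with low PD cells to describe an intermediate passage that is not described as senescent. Here too passage, library and the barcode difference cannot be told apart. Cell cycle genes were lower. The G2/M list had a median log2 ratio of -1.17 (-1.48 to -0.28) with 30 of 37 members lower. The S phase list had -0.44 (-0.72 to -0.26) with 24 of 28, and the list of genes known to be lower in senescent cells -0.81 (-1.04 to -0.34) with 11 of 12. TOP2A, the topoisomerase of dividing cells, was at 19.5 CPM (13.8 to 26.7) against 107 (91.1 to 124). HMGB2 had -0.99 (-1.43 to -0.56) and MKI67 -0.79 (-1.51 to -0.10), although 1 high PD barcode held 52.6% of the TOP2A and 51.6% of the MKI67 UMIs. LMNB1 had 2 against 14 UMIs (-2.86, -6.32 to -1.01).

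Immediate early genes were lower in 23 of 25 cases (median -0.77, -1.27 to -0.59), with FOS at 69.7 CPM (58.5 to 82.5) against 545 (509 to 583), FOSB at -3.13 (-3.73 to -2.61), and NR4A1 at -3.07 (-4.00 to -2.32). EGR1 was at -2.33 (-2.61 to -2.06). As a sum the immediate early list was highest in low PD cells, at 3237.5 CPM. It was at 2266.6 in irradiated, 1399.7 in high PD and 1666.8 in replicative senescent cells. The lower medians against low PD cells share that 1 library, so they are not separate observations. A trait of the low PD library cannot be told apart from an effect of passage or irradiation. Ribosomal protein genes were lower in 72 of 76 cases (median -0.63, -0.69 to -0.59). Secretory genes had a median of 0.66 (0.34 to 1.15, 24 of 31 higher), among them PLAU (2.57, 2.05 to 3.17), PLAT (2.52, 2.29 to 2.76), IGFBP2 (2.46, 2.15 to 2.81) and ICAM1 (2.0, 1.30 to 2.82). IL6 had 0.52 (0.04 to 1.02), MMP1 1.62 (-0.07 to 4.24), IL8 1 and 2 UMIs and MMP3 none in either library. Targets of p53 had a median of 0.45 (0.10 to 0.76, 26 of 33 higher), with DDB2 at 1.63 (1.18 to 2.13) and AEN at 1.11 (0.47 to 1.82). GDF15 was at 0.81 (0.09 to 1.60), MDM2 at 0.71 (0.41 to 1.02) and CDKN1A at 0.34 (0.15 to 0.54). CDKN2A was at 57.4 CPM (47.3 to 69.1) against 32.1 (23.9 to 42.4, 0.83, 0.34 to 1.35).

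Matrix genes had a median of 0.24 (0.04 to 0.45, 40 of 57 higher), with COL6A1 at 1.98 (1.88 to 2.09), COL11A1 at 1.44 (0.98 to 1.95), MGP at 1.44 (1.24 to 1.65) and fibronectin, FN1, at 1.28 (1.22 to 1.34). COL1A1 had -0.13 (-0.16 to -0.10) and COL3A1 0.01 (-0.09 to 0.10), the last turning below 0 with trimmed mean scaling. Fibroblast markers had a median of 0.24 (0.01 to 0.64), lysosomal genes 0.36 (0.15 to 0.50, 36 of 46 higher), MHC class I genes 0.40 (0.26 to 0.52) and interferon-stimulated genes 0.29 (-0.15 to 0.58). The contractile list had 0.38 (0.09 to 0.61), beside ACTA2 at 0.61 (0.47 to 0.75) and pericyte and smooth muscle markers at 0.79 (0.53 to 4.85). The highest ratios outside these groups were the noncoding RNA DIRC3 (3.45, 3.02 to 3.94), ANKRD1 (3.10, 2.68 to 3.58), KRT18 (2.5, 2.09 to 2.96, 23.5% of the low PD UMIs in 1 barcode) and DEGS1 (2.44, 2.08 to 2.85). Further ones were NTN4 (2.40, 2.13 to 2.69), the hypoxia-inducible EPAS1 (2.31, 2.03 to 2.60) and ACAN (2.15, 1.91 to 2.39). The other lowest were FAM211A (-2.22, -2.47 to -1.98), NREP (-1.56, -1.69 to -1.44), C4orf3 (-1.55, -1.82 to -1.29), ZFP36L1 (-1.46, -1.60 to -1.31) and ANP32B (-1.43, -1.59 to -1.27). The matched random lists put the G2/M, ribosomal protein and immediate early medians at percentile 0, S phase at 0.01, the secretory list at 100 and p53 targets at 99.82. The G2/M median was -0.62 among members of at least 100 UMIs.

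Replicative senescent cells were next compared with high PD cells, the nearest earlier passage. COL8A1 was at 2987 against 30.2 CPM (log2 ratio 6.61, 6.26 to 7.02), STMN2 had 6.89 (6.07 to 8.02), SERPINB2 7.61 (6.28 to 10.11) and PCDH10 7.49 (5.95 to 10.86). ACTC1, with no UMI in high PD cells, was at least 184-fold higher. EGFL6 was at least 107-fold lower, the complement component C3 had -7.69 (-13.58 to -5.78) and the tight junction gene CLDN11 -7.15 (-10.52 to -5.61). The aldo-keto reductases AKR1C1 and AKR1C3, close paralogs whose reads can be shared, had -6.10 (-7.67 to -5.08) and -6.11 (-8.16 to -4.91). CDKN1A was higher (1.39, 1.25 to 1.54) and CDKN2A lower, with 14 against 112 UMIs (-2.71, -3.67 to -1.95). Ribosomal protein genes were lower in 76 of 76 cases (median -0.76, -0.81 to -0.70) and cholesterol synthesis genes higher in 17 of 20 (0.91, 0.63 to 1.5). The G2/M median was 1.03 (0.78 to 1.70) with 37 of 41 members higher, and 0.60 without the top barcode of each library.

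Secretory genes went both ways between these libraries (-0.33, -0.64 to 0.28, 21 of 35 lower), with MMP3 at least 41.9-fold higher and MMP1 at 2.29 (1.44 to 3.33). FGF7 (-3.56, -3.93 to -3.23), PLAT (-3.25, -3.56 to -2.98) and IL6 (-1.93, -2.69 to -1.27) were lower. Matrix genes had a median of -0.13 (-0.69 to 0.18), with FBN2 (-3.08, -3.43 to -2.75), FBLN1 (-3.07, -3.21 to -2.94), COL6A1 (-2.96, -3.11 to -2.83), COL1A1 (-0.82, -0.86 to -0.79) and COL3A1 (-0.69, -0.80 to -0.59) lower. Medians were 0.27 (0.02 to 0.47) for lysosomal genes and 0.11 (-0.20 to 0.40) for p53 targets. They were 0.09 (-0.30 to 0.68) for interferon-stimulated genes (below 0 with the total taken without mitochondrial and ribosomal protein genes), 0.11 (-0.82 to 0.91) for immediate early genes (below 0 without barcodes of over 2 times the median UMIs), 1.09 (0.12 to 2.37) for histones and 0.13 (0.10 to 0.26) for oxidative phosphorylation. GDF15 had 0.80 (0.27 to 1.35), MDM2 0.38 (0.14 to 0.62), ACTA2 -1.31 (-1.47 to -1.14), HMGB2 1.16 (0.76 to 1.59), and LMNB1 6 and 2 UMIs. TOP2A had 1.89 (1.37 to 2.47), resting on 1 barcode as above, which turned to -0.51 in a random draw of 50% of the cells. Genes known to be lower in senescent cells had a median of 0.61 (-0.11 to 1.16, 8 of 12 higher). Homologous recombination had 0.66 (-0.20 to 1.095, 9 of 11 higher). Random lists put these medians at percentiles 99.57 and 99.70, the secretory median at 0.49, the ribosomal protein median at 0 and the G2/M median at 100.

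Replicative senescent cells were also set directly against irradiated cells, which their label names by dose and not as senescent. Secretory genes were lower in replicative senescent than in irradiated cells, with a median log2 ratio of -0.86 (-1.61 to -0.42) and 32 of 44 members lower. IL8 had no UMI in senescent cells, at least 78.4-fold lower than the 143 (127 to 161) CPM after irradiation, and CXCL1 was at least 71.9-fold lower. CXCL6 (-8.26, -14.14 to -6.35), PLAT (-3.85, -4.15 to -3.58), IL6 (-1.53, -2.31 to -0.86), GDF15 (-1.61, -2.01 to -1.24) and MMP1 (-0.83, -1.32 to -0.36) were lower, with the shares of CXCL6 and CXCL1 in 1 irradiated barcode as given above. CCL5 was at least 72.7-fold lower on the strength of 1 irradiated barcode with 91.8% of its UMIs. CLDN11 was lower as well (-6.03, -9.40 to -4.47), and MMP3 was higher (3.11, 2.34 to 4.07). CDKN1A differed little, at 741 CPM (699.9 to 784) against 641 (606 to 678), and MDM2 had -0.03 (-0.26 to 0.19), while CDKN2A had -1.51 (-2.52 to -0.66).

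Matrix genes were higher in replicative senescent cells (median 0.75, 0.05 to 1.01, 36 of 55 higher), with MFAP4 (4.74, 3.76 to 6.17), COL8A1 (4.29, 4.12 to 4.47), MGP (4.04, 3.68 to 4.43), COL11A1 (3.73, 3.39 to 4.12) and COL1A1 (0.65, 0.59 to 0.69) among them. STMN2 (8.94, 7.41 to 12.31), SLC38A11 (7.91, 6.58 to 10.41), ACTC1 (7.77, 6.23 to 11.14), PCDH10 (6.09, 5.07 to 7.66) and the collagen-binding integrin ITGA11 (5.35, 4.68 to 6.21) had the highest ratios. Ribosomal protein genes (-0.85, -0.95 to -0.77), proteasome genes (-0.42, -0.56 to -0.26), and oxidative phosphorylation genes (-0.33, -0.44 to -0.22) were lower as groups. Immediate early genes (-0.69, -1.46 to -0.14) were lower too, with MYC at -2.55 (-3.51 to -1.78) and FOSL1 at -2.21 (-2.75 to -1.74) but FOS at 1.68 (1.37 to 2.0). Targets of p53 (-0.13, -0.62 to 0.11), interferon-stimulated genes (-0.12, -0.33 to 0.24), lysosomal genes (-0.13, -0.48 to 0.13) and glycolysis genes (-0.39, -1.0 to 0.06) showed no clear direction. The G2/M median was 0.39 (0.14 to 0.63), and -0.28 without the top barcode of each library. The S phase median of -0.41 (-0.72 to 0.16) turned to 0.13 without barcodes of over 2 times the median UMIs. Random lists placed the secretory, ribosomal protein and immediate early medians at percentile 0, the matrix median at 100 and the proteasome median at 0.16.

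The ratios of the irradiated and the replicative senescent library to low PD cells were compared across 9559 genes, with a Pearson correlation of 0.477 and a covariance of 0.468. The ratio of high PD to low PD cells had a correlation of 0.450 with that of replicative senescent cells and 0.341 with that of irradiated cells. Genes are not independent replicates, and all of these ratios share the low PD library. All 4 libraries were also drawn 100 times, as unchanged groups, from 1 profile pooled over them. The first pair of ratios then had a mean correlation of 0.533 and a mean covariance of 0.059. These draws hold counting error only and were read for the first pair and for the pair without a shared library given below. The observed log2 ratios had SDs of 0.872 in irradiated, 1.125 in replicative senescent and 0.680 in high PD cells. The simulated correlation is therefore no baseline for 0.477, 0.450 or 0.341, which are not read as likeness. Of 865 genes with a log2 ratio over 1 in size in both ratios of the first pair, 780 went the same direction. Their shared low PD library can also favour this. The covariance of the first pair exceeded the simulated one by 0.409, and part of the excess may come from the low PD library, which cannot be split. The ratio of irradiated to low PD cells and that of replicative senescent to high PD cells share no library. They had a correlation of 0.298 and a covariance of 0.266. The draws are independent, so these ratios are uncorrelated in them by design (mean correlation 0.001). Counting error alone thus does not give 0.298. Which differences between the libraries give it was not tested, so it is not read as likeness.

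Shares of cells with a transcript were compared after thinning every cell to 2000 UMIs, which left 295 low PD, 352 irradiated, 330 high PD and 263 replicative senescent cells. A UMI of CDKN1A was found in 35.9% (30.4 to 41.7), 65.1% (59.8 to 70), 38.8% (33.5 to 44.3) and 73.4% (67.6 to 78.6) of cells in that order. Without thinning it was found in 49.2%, 79.0%, 60% and 77.3%. CDKN2A was found in 5.42% (3.13 to 8.66), 5.11% (3.06 to 7.96), 11.5% (8.28 to 15.5) and 1.90% (0.62 to 4.38), unthinned 10.4%, 9.75%, 18.9% and 3.48%. IL8 was found in 14.5% (11 to 18.6) of irradiated cells, in 1 cell each of the low PD and high PD libraries, and in 0 of 263 replicative senescent cells, where 3 counts, the limit taken for a count of 0, allow a share of cells with a UMI of up to 1.14%, and unthinned in 20% of irradiated cells. GDF15 was found in 4.07% (2.12 to 7.0), 19.3% (15.3 to 23.8), 5.76% (3.50 to 8.85) and 6.84% (4.11 to 10.6), unthinned 4.82%, 24.8%, 11.1% and 12.6%. The S and G2/M transcript TOP2A was found in 8.47% (5.56 to 12.3), 7.95% (5.35 to 11.3), 2.12% (0.86 to 4.32) and 2.66% (1.08 to 5.41) of cells, unthinned 11.9%, 12.5%, 3.78% and 4.55%, and MKI67 in 4.75%, 3.69%, 1.52% and 1.90%, unthinned 5.33%, 5.50%, 2.02% and 2.67%. COL1A1 was found in 100%, 94.3%, 99.7% and 97.0% and COL3A1 in 79.7%, 54.6%, 78.5% and 72.6% (unthinned 100%, 96.0%, 99.2% and 96.8% and 89.8%, 69.0%, 90.2% and 78.6%). IL6 (5.76%, 7.39%, 8.18% and 4.18%, unthinned 9.14%, 12.5%, 16.6% and 5.08%) and LMNB1 (2.03%, 0.85%, 0% and 0.76%, unthinned 2.54%, 2.0%, 0.50% and 0.80%) had overlapping intervals. MMP1 was found in 0%, 8.52%, 0.61% and 4.94% (unthinned 0.76%, 13.0%, 1.51% and 8.29%) and MMP3 in 0%, 1.70%, 0% and 6.08% (unthinned 0%, 2.75%, 0% and 8.29%). Free RNA adds UMIs to cells that do not express a gene, and no cell type lacking these genes was present to measure it, so low shares cannot be told from background.

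The correlation between cells was lower in the replicative senescent than in the low PD library. It also depends on how UMIs are spread over genes, which differed between the libraries. Ribosomal protein genes took 17.3% of UMIs in low PD and 6.74% in replicative senescent cells. No value expected of 1 population was simulated per library, so the correlation is not read as a difference in how alike the cells were. Over 263 cells of 2000 UMIs from each library and 1000 genes, the median correlation between pairs of cells was 0.556 (0.548 to 0.564) in low PD cells, 0.510 (0.498 to 0.521) after irradiation, 0.493 (0.488 to 0.499) in high PD cells and 0.433 (0.427 to 0.439) in replicative senescent cells. The median squared coefficient of variation beyond Poisson error ordered them otherwise, at 0.252, 0.252, 0.184 and 0.206. That order did not hold, since replicative senescent cells were highest at 1000 UMIs per cell (0.246, 0.213, 0.189 and 0.247) and with 300 genes (0.153, 0.167, 0.143 and 0.188). The leading axis of variation held 3.24% of the variance in low PD cells, 5.43% after irradiation, 4.99% in high PD cells and 3.94% in replicative senescent cells, against 0.92% to 0.99% after permuting each gene. Its ends were collagens (COL1A1, COL1A2) and the iron-storage gene FTH1 against actin and contractile genes (ACTB, TAGLN) in low PD cells, and the nuclear RNAs NEAT1 and MALAT1 against MT2A, TIMP1 and LGALS1 after irradiation. They were THBS1 and FN1 against FTH1 and ribosomal protein genes in high PD cells, and TAGLN, TPM1 and ELN against ALDH1A1, MGP and STMN2 in replicative senescent cells. Of the 30 leading genes, 17, 20, 18 and 5 were also leading at 1000 UMIs per cell.

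Clustering of all thinned cells gave 6 clusters, each mostly of 1 library, so a cluster may be a library rather than a cell state. Cluster 3, led by EGR1 and FOS, held 94.2% of low PD cells, cluster 1, led by ACAN and DIRC3, 95.5% of high PD cells and cluster 2 85.8% of irradiated cells, and cluster 6 held another 11.1% (8.0 to 14.8) of irradiated cells. The leading genes were CCL5, CCL3, IL8, TSLP and GDF15 in cluster 6, with CCL5 resting on 1 barcode. Replicative senescent cells were divided between cluster 4 (50.2%, 44.0 to 56.4), led by ACTC1, PCDH10, COL11A1 and PLCB4, and cluster 5 (49.4%, 43.2 to 55.6), led by STMN2, SLC38A11, CD36 and COL8A1. No cluster was given a cell type name. At a lower resolution of 0.25, replicative senescent cells formed 1 cluster of 98.9% of them, and after joining barcodes 1 base apart the shares of clusters 4 and 5 were 51.3% and 48.3% and that of cluster 6 8.93%.

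**Figure D3:**
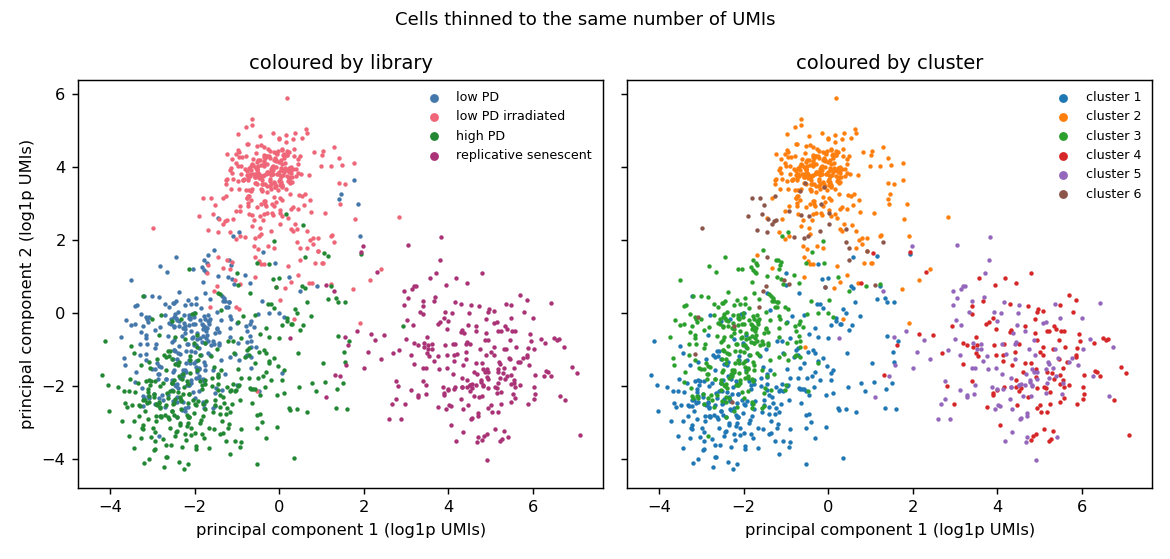
Positions of the cells, thinned to 2000 UMIs, on the leading principal components of log1p UMI counts, coloured by library (left) and by cluster (right). Each point is 1 cell, and the replicative senescent cells lie apart from the other libraries and the points of clusters 4 and 5, with 50.2% and 49.4% of these cells, overlap on these axes.

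**Figure D4:**
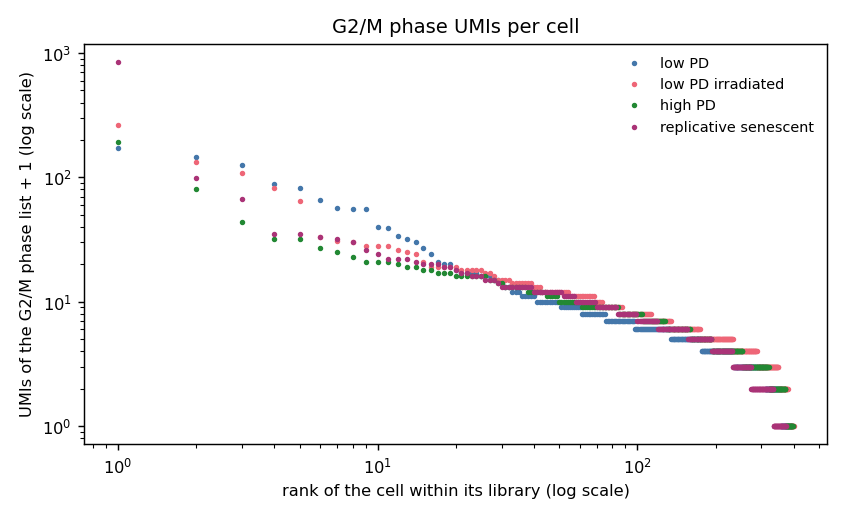
UMIs of the G2/M phase list in each cell plus 1 (vertical, log scale) against the rank of the cell within its library (horizontal, log scale), for the 4 libraries. Each point is 1 cell, and the first replicative senescent cell holds 844 of the 2898 UMIs of the list in its library.

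Cells of each library were also split into 2 sides on 2 disjoint sets of genes, a description added after the clusters were seen. It gives 2 sides for any cells and does not tell separate sets from a gradient. The splits put 92.8% of replicative senescent cells on the same side (lowest 89.4 and highest 93.9 of 20 divisions of the genes), against 51.3% after permuting. Sides were 123 and 124 cells, with medians of 5135 and 3741 UMIs. The first side had more MGP, a matrix calcification inhibitor (log2 ratio 4.26, 3.77 to 4.85), MMP3 (4.88, 3.31 to 8.26), KRT19 (3.99), CD36 (3.52), STMN2 (3.08), SLC38A11 (2.97) and ALDH1A1 (2.32). The other side had more of the smooth muscle actin ACTA2 (-3.70, -4.25 to -3.23), POSTN (-3.34), NTM (-3.01), and PLCB4 (-2.79). It also had more ACTC1 (-2.50), INHBA (-2.21), COL11A1 (-2.18), ELN (-1.77) and COL1A1 (-1.23, -1.30 to -1.15). Between these sides the YAP target list had a median of -0.55 (-0.72 to -0.33) with 0 of 18 members higher on the first side, and the lysosomal list 0.47 (0.30 to 0.64) with 37 of 42. The mitochondrially encoded list had 0.61 (0.50 to 0.86) with 13 of 13 and the cholesterol synthesis list 0.72 (0.15 to 0.83) with 16 of 18. Pericyte and smooth muscle markers had -0.94 (-3.70 to 2.80, 3 of 5 lower) and the contractile list -0.59 (-1.23 to 0.04, 16 of 22 lower), at percentiles 0.03 and 0 among random lists. The G2/M list, at 1.07, rests in part on the barcode with 844 of its UMIs.

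Irradiated cells were put on the same side in 95.7% of cases (93.5 to 97.4). In the first division both sets put 56 and 283 of them on the 2 sides, with medians of 3725.5 and 2800 UMIs. The smaller side had more GDF15 (3.07, 2.69 to 3.46), DDIT3 (2.45), ATF3 (2.53), IL8 (2.23), MDM2 (1.81) and NEAT1 (1.61), and more CCL5 on the strength of 1 barcode. Its p53 targets had a median of 0.85 (0.49 to 1.18, 30 of 33 higher), the unfolded protein response list 0.69 (0.45 to 1.09, 23 of 24), ribosomal protein genes -0.75 (-0.80 to -0.69, 76 lower) and oxidative phosphorylation genes -0.52 (-0.66 to -0.33, 61 lower). The smaller side also had more mitochondrially encoded transcripts (median 0.78, 0.61 to 0.89, 13 of 13) and MALAT1 (0.83, 0.79 to 0.86), of the S phase list (0.86, 0.53 to 1.44, 21 of 23) and of the G2/M list (0.85, 0.44 to 1.10, 23 of 28). More mitochondrial and nuclear RNA is also known from damaged cells, so RNA quality was not separated from the p53 and stress difference. The larger side had more LGALS1 (-1.41), RGS4 (-1.65) and MT2A (-1.26). Low PD cells were put on the same side in 88.1% of cases (60 to 92.2). Both sets put 56 of them on the smaller side, with a median of 5111 UMIs, and 195 on the other, with 2993. By the ratios, read over all 295 cells, the smaller side had more transcripts of the G2/M list, with a median of -1.25 (-1.96 to -0.91, 30 of 30). It had more of the contractile list (-0.70, -1.02 to -0.36) and less of the matrix list (0.39, 0.18 to 0.61). It also had more of the pericyte and smooth muscle markers (-1.45, 3 of 3) and mitochondrially encoded genes (-0.36, 12 of 13) and less of the ribosomal protein genes (0.38, 76 of 76).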

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

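Of the genes with the 10 highest or 10 lowest ratios in the comparisons of irradiated or replicative senescent with low PD cells, 3 differed in opposite directions in these libraries, with counting intervals on opposite sides of 0. These differences were not tested, since each library is 1 sample. PLAT had a log2 ratio of 3.11 after irradiation and -0.74 in replicative senescent cells, a difference of 3.85. RGS4 had 3.30 and -1.33, a difference of 4.63. THBS2, a matrix glycoprotein, had -2.72 and 0.87, a difference of -3.58.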

How the results depend on the processing

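Of the alternatives given here, those chosen after the data were seen are the removal of each library's barcode with the most G2/M UMIs and the merging of barcodes 1 base apart. No paired analysis was possible because each group was 1 library. Over the alternatives, 1975 of 2025 list medians stayed within the interval of the reported value, 47 lay outside it and 3 reversed, and 7306 of 7848 gene ratios stayed within, 535 lay outside and 7 reversed. Reversed is a change of sign where the median lay beyond the central 95% of random lists or the interval of the ratio excluded 0. With or without that, 110 of the 2025 medians changed sign, 18 of them without barcodes of over 2 times the median UMIs and 18 in the random draw. The cause was not tested, except where the removal of a barcode shows it.

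Without barcodes of over 2 times the median UMIs, the S phase median of replicative senescent against irradiated cells reversed to 0.13, XRCC5 to -0.002 (irradiated against low PD), DAXX to 0.034 (replicative senescent against low PD) and 0.10 (high PD against low PD) and TOP2A to -0.41 (replicative senescent against irradiated). The G2/M medians moved to -0.61 (irradiated against low PD) and 0.55 (replicative senescent against high PD), the lysosomal median of high PD cells to 0.51 and their ribosomal protein median to -0.70. With members of at least 100 UMIs the S phase median of replicative senescent against irradiated cells reversed to 0.16. In a random draw of 50% of the cells, oxidative phosphorylation in high PD cells reversed to 0.04 and TOP2A to -0.51 (against high PD) and -1.35 (against irradiated), and the G2/M median was 0.20 against high PD and -0.064 against irradiated cells. With every cell weighing the same, the G2/M medians of replicative senescent cells were -0.37 against low PD, 0.64 against high PD and -0.14 against irradiated cells. Without the top G2/M barcodes these were -0.54, 0.60 and -0.28, and TOP2A against irradiated cells reversed to -0.96.

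The ribosomal protein median, lower under all of these settings, was -0.70 with trimmed mean, -0.68 with median-of-ratios and -0.69 with totals without mitochondrial and ribosomal protein genes in irradiated cells, -1.57, -1.54 and -1.57 in replicative senescent cells, -0.75, -0.73 and -0.74 in high PD cells, and -0.83, -0.83 and -0.84 in replicative senescent against high PD cells (-0.83 with every cell weighing the same). At 1000 UMIs per cell the correlation between cells was 0.484, 0.425, 0.415 and 0.362 in low PD, irradiated, high PD and replicative senescent cells, and with 300 genes 0.577 in low PD, 0.496 in irradiated and 0.451 in replicative senescent cells. The leading axis held 2.38%, 3.52% and 3.48% in low PD, irradiated and replicative senescent cells at 1000 UMIs, and 4.45% in irradiated cells with barcodes merged. Clusters of at least 10% of a library numbered 1 in irradiated and 1 in replicative senescent cells at resolution 0.25, 2 in low PD and 2 in high PD cells at 1.0, and 1 in irradiated cells with barcodes merged. With at least 200 UMIs per gene the irradiated and replicative senescent ratios to low PD had a correlation of 0.431 and a covariance of 0.330, for which no unchanged groups were drawn. Depth limits genes of few UMIs: 3 counts, the limit taken for a count of 0, are 1.93, 1.56, 1.54 and 1.83 CPM in low PD, irradiated, high PD and replicative senescent cells.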

Other observations

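Tests chosen only after the result was seen are the TOP2A and MKI67 shares, the markers of other cell types on the sides, HOXC10, the oxidative phosphorylation list as a measure of nuclear RNA, the tests on ribosomal protein genes in irradiated and high PD cells, the removal of top barcodes, the merging of barcodes and the splits. Of 4 genes picked singly after their values were seen, which stand for no group, HOTAIR had 13 UMIs in low PD, 22 in irradiated, 17 in high PD and 189 in replicative senescent cells, and HOXC10 14, 17, 14 and 98. The strand counted is not given, so either count may include an overlapping antisense gene. PITX1 had 61, 21, 72 and 3 and TWIST1 131, 45, 120 and 44.

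The G2/M list was not lower in replicative senescent than in low PD cells by the summed counts, with a median of 0.36. Without each library's top G2/M barcode it was -0.54, so 1 barcode accounts for the sign. With the total taken without mitochondrial and ribosomal protein genes the median was 0.16, which leaves a part of the scaling open. Cells with a TOP2A UMI were 2.66% (1.08 to 5.41) in replicative senescent and 8.47% (5.56 to 12.3) in low PD cells, but those with MKI67 overlapped, at 1.90% (0.62 to 4.38) and 4.75% (2.62 to 7.83). Free RNA was not measured, so as large a share of cycling cells stays open. Whether the barcode was 1 cycling cell or several cells in 1 droplet cannot be told from its 29051 UMIs.

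Replicative senescent cells were split into 2 sides alike on disjoint genes, which does not tell 2 sets from a gradient. Their depth was argued against, since 91.0% of 122 cells of 2000 to 4000 UMIs were put on the same side. The split did not rest on mitochondrial, ribosomal and nuclear RNA genes or on the cell cycle lists. Without them 93.2% and 92.6% of cells were put on the same side. Other genes can shift with RNA content or the cell cycle, so both stay open. Mitochondrially encoded genes were higher on the first side in 13 of 13 cases and G2/M genes in 29 of 32. The G2/M count rests in part on the barcode with 844 of the 2898 UMIs of that list in the library. Immune, endothelial and erythroid markers held 7, 13 and 2 UMIs in the library, fewer than the 123 cells of the smaller side, which argues against cells of these types. Pericyte and smooth muscle markers differed by a median of -0.94 (-3.70 to 2.80), which leaves such cells open. HOXC10 differed by 4.22, so a mixture of fibroblast cultures in the library and separate states of 1 culture could not be told apart. As a hypothesis, the sides may be separate clones, states or ends of a gradient of senescent fibroblasts, for which no test was available.

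Ribosomal protein genes were lower in the other 3 libraries than in low PD cells. Scaling did not remove this, at -0.70 in irradiated, -0.75 in high PD and -1.57 in replicative senescent cells with trimmed mean factors. The 1250 other genes of like transcript length had medians of 0.17, 0.059 and 0.20 in that order, which argues against a loss of short transcripts. Nuclear-encoded oxidative phosphorylation genes, whose cytoplasmic transcripts would be lower with more nuclear RNA, had 0.55, -0.081 (40 of 67 lower) and 0.20, which argues against more nuclear RNA as the whole cause. A lower level of ribosomal protein transcripts in later passages and after irradiation is a hypothesis that may hold, and library and group remain confounded.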
